A study of Homo sapiens with 12 samples.

How the data were processed

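Total RNA from human ovarian cancer cell lines was measured on 12 single-colour arrays after transfection with an siRNA against NR2F2 or with a non-targeting siRNA. Per the labels, cells were harvested 48 hours after transfection with a lipid reagent, the RNA was treated with DNase, and biotin was the label. The deposited table holds 1 intensity per probe and array, for 48803 probes whose identifiers follow the Illumina pattern. The intensity values are on a linear scale and all lie above 0, with a smallest value of 53.0. Every column of the deposited intensity table has the same mean, 926, so the arrays had been scaled to 1 mean before deposit. Scanner software, background handling and the method of scaling are not given in the sources used here, and detection p-values were not used here.

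Array medians still differed by up to 0.24 on the log2 scale. The rule, fixed before the data were examined together with the tests, the filter and most alternatives, was to quantile-normalize the log2 values where this gap exceeded 0.1, and that was done. A floor of 16 on the intensity touched 0 values. A probe was tested when its log2 value exceeded the median of all values, 6.88, on at least 3 of the 12 arrays. This kept 28257 probes (57.9%) and left out 20546 dim ones, for which no statement is made.

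Groups came from the labelled cell line and siRNA, giving 4 groups of 3 arrays. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 12 arrays, with 8 residual degrees of freedom. The contrasts were the knockdown within each line, the difference between these effects, their mean, and ES2 against TOV112D among the non-targeting arrays. Tests were two-sided limma moderated tests with Benjamini-Hochberg adjustment within each contrast, and a probe was called at an adjusted p under 0.05. Overlaps between lines were tested with a one-sided Fisher exact test per direction. Pooling the spread over both lines assumes that it is alike in them. Where an array is left out, the 2 arrays remaining in its group are assumed to vary like the others. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

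The titles number the arrays 1, 2 and 4 in TOV112D and 3, 4 and 5 in ES2, with the same numbers in both siRNA groups. Deviations from the group means correlated between same-numbered arrays across the tested probes at r = 0.48, 0.32 and 0.79 in TOV112D and at 0.30, 0.27 and 0.63 in ES2. All 6 exceeded 0.1, the value set for treating the numbers as pairs. However, the highest correlation was with the array of the same number for only 3 of the 6 knockdown arrays. The highest correlation with another number was 0.51 and 0.41 for TOV112D numbers 1 and 2, and 0.28 and 0.32 for ES2 numbers 3 and 4. The check thus clearly matched only number 4 of TOV112D and number 5 of ES2. For the other numbers a correlation above 0.1 is no evidence of pairing. Deviations cancel out within a group, so 1 number standing apart can make the other arrays correlate whatever their numbers. The set rule was still followed. A model with the number as a block within each line (4 residual degrees of freedom) was set beside the results it changed.

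On simulated values for the 28257 tested probes, with 200 of them changed, the model without the block recovered 58.2% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes in TOV112D, with 0 false calls. In ES2 it recovered 52.2%, 91.0% and 100% of them, also with 0 false calls. The model with the block recovered 98.5% and 94.0% of the 1.5-fold changes in TOV112D and ES2. Its false calls were 71 of 270 in TOV112D and 4 of 200 in ES2. The median SD under the block was 0.11 in TOV112D and 0.09 in ES2 on the log2 scale, and the calls of this model in TOV112D carry less weight. The averaged contrast was not simulated. Simulated noise was normal and independent between probes, and no array was made to stand apart. Same-numbered simulated arrays had 0.76 of their noise variance in common in TOV112D and 0.58 in ES2. That favours recovery with the block. It also makes the model without the block cautious, so its 0 false calls partly follow from this setting. On the real arrays the block lowered the median SD from 0.15 to 0.11 in TOV112D and from 0.11 to 0.09 in ES2. So much common noise would lower it further. The recovered shares can therefore overstate what the real arrays allow. In the real TOV112D arrays a 6.14-fold difference, that of ILMN_2094360, did not pass (limma adjusted p = 0.212).

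No table pairing these probes with genes was used here, and the reference table of gene names holds none of the probe identifiers, so all results are given per probe. The planned check of NR2F2 itself, the choice of 1 probe per gene and the tests of 30 gene lists were therefore not run. Probe identifiers were chosen by the rule fixed beforehand: within each contrast, those with the largest change among called probes whose same-numbered differences all had the fitted direction, or among probes at an unadjusted p under 0.01 where none passed in a direction. The rule was shortened to 2 identifiers that rose and 2 that fell in all. For the averaged contrast the rule, with all 6 differences in 1 direction, was set after its values were seen.

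Alternatives were other normalizations, other filters, a floor of 64, separate fits per line, the block, trended and robust moderation, array weights, stricter thresholds and leaving out each array in turn. A few combinations were added after the data were seen.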

Results

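NR2F2, also called COUP-TFII, is an orphan nuclear receptor that acts as a transcription factor. Its knockdown by siRNA was compared with a non-targeting siRNA in TOV112D, a line derived from an endometrioid ovarian carcinoma, and in ES2, a line described as ovarian clear cell carcinoma. RNA was taken 48 hours after transfection, and an siRNA concentration of 25 nM is stated for ES2. Each of the 4 groups held 3 arrays, and 28257 probes were tested on each array. The files do not pair the probes with genes, so the level of NR2F2 in each array could not be read and the labels were not checked in that way.

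The cell line separated the arrays most. The first principal component, with 87.7% of the variance, parted TOV112D from ES2, and the highest correlation between arrays of different lines was 0.881. Within TOV112D the second component (5.25%) set both number 4 arrays apart, at 38.7 and 38.9, from the others, all below 0. The third component (2.51%) set the NR2F2 siRNA array number 2 apart, at 34.7. Its correlations with the other TOV112D arrays were at most 0.986, whereas the remaining arrays of numbers 1 and 2 correlated at 0.997. Within ES2 the fourth component (1.56%) set the number 5 arrays apart, at 20.1 and 22.8. As groups, knockdown and control arrays of TOV112D overlapped on each of these 4 components. Those of ES2 overlapped on all but the first, where knockdown arrays lay at 81.3 to 82.5 and control arrays at 80.6 to 81.3. Within same-numbered pairs the knockdown array scored lower on the second component in all 6, by differences of -0.823, -23.4 and -0.218 in TOV112D and -1.43, -5.72 and -0.267 in ES2. It scored higher on the third component in all 3 TOV112D pairs and lower on the fourth in all 3 ES2 pairs. These shifts were not tested. The median SD within groups was 0.15 on the log2 scale in TOV112D and 0.11 in ES2.

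**Figure D1:**
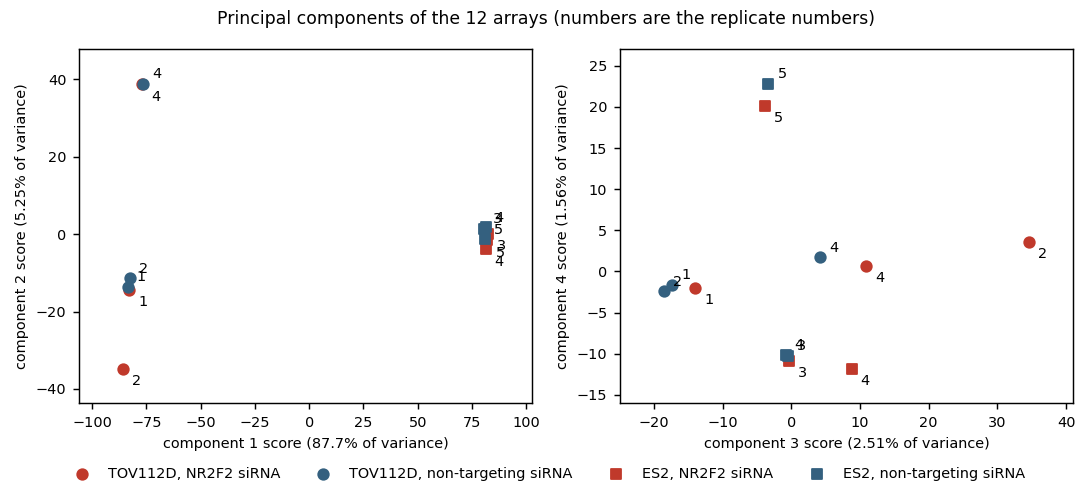
Principal component scores (no unit) of the 12 arrays from the normalized log2 intensities of tested probes, components 1 and 2 at left and 3 and 4 at right. Circles are TOV112D, squares ES2, red NR2F2 siRNA, blue non-targeting siRNA, and digits are the replicate numbers; component 1 holds 87.7% of the variance and parts the lines, and same-numbered arrays 4 of TOV112D and 5 of ES2 lie together.

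In TOV112D, which transcripts responded to NR2F2 knockdown was asked with 3 arrays per siRNA. No probe passed the threshold in limma (0 of 28257, smallest adjusted p = 0.212), and 1187 probes had an unadjusted p under 0.05 where 1413 are expected by chance. With the replicate block that number was 3258, and 1593 with the line fitted alone with the block. A count below chance is not evidence that no transcript responded, since the model without the block counts differences between array numbers as spread. The largest difference among probes at an unadjusted p under 0.01 was that of ILMN_2094360. Its log2 intensity was 10.85 ± 0.16 (SD, n = 3) with the non-targeting siRNA and 8.23 ± 0.69 (SD, n = 3) with the NR2F2 siRNA, a log2 difference of -2.62 (SE 0.34) or 6.14-fold. It was lower in all 3 same-numbered comparisons, by log2 differences of -2.52, -3.28 and -2.05 for numbers 1, 2 and 4. Among the 92 probes higher at that unadjusted p, ILMN_2340908 had the largest difference, 0.62 (SE 0.13, limma adjusted p = 0.974), positive in each of the 3 comparisons. With the replicate block 2 probes were called, both lower, ILMN_2094360 among them (limma adjusted p = 0.0161, and between 0.00023 and 1.000 over all settings tried). On simulated values that model gave 71 false calls of 270 in this line.

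In ES2, the same contrast called 8 probes, 6 higher and 2 lower with the NR2F2 siRNA. The 6 rises lay between 0.57 and 1.30 on the log2 scale, the 2 falls were -0.84 and -1.22, and 3 of the 8 reached 2-fold. All 8 had the same direction in each of the 3 same-numbered comparisons, which use the arrays that gave the calls and are not separate support. ILMN_2075643 rose 2.45-fold, from 7.99 ± 0.28 to 9.29 ± 0.10 (SD, n = 3 each; log2 difference 1.30, SE 0.16, limma adjusted p = 0.0240), with differences of 1.41, 1.40 and 1.08 for numbers 3, 4 and 5. ILMN_1745785 fell 2.33-fold, from 8.56 ± 0.16 to 7.35 ± 0.27 (SD, n = 3 each; log2 difference -1.22, SE 0.14, limma adjusted p = 0.0227), with differences of -1.33, -1.23 and -1.10. ILMN_2094360 did not pass, at a log2 difference of -2.23 (SE 0.34, 4.68-fold, limma adjusted p = 0.0568), with differences of -2.48, -2.75 and -1.45.

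With the replicate block 104 probes were called in ES2, 64 higher and 40 lower, and these included the 8. Rises then lay between 0.46 and 1.30 and falls between -0.46 and -2.23. All 104 had 1 direction across the 3 pairs, from which the calls themselves were made. Of the 104, 8 reached 2-fold, and ILMN_2094360 was among the 104. The count without the block moved with single arrays: it was 0 without any of the ES2 arrays of number 3 or number 4 or without the TOV112D non-targeting array 2, and 1 without the TOV112D non-targeting array 1. It was 31 without the ES2 NR2F2 siRNA array 5, 13 without the ES2 non-targeting array 5, and 15 and 13 without the TOV112D NR2F2 siRNA arrays 2 and 4. The fold changes moved less: over all settings the log2 difference lay between 1.20 and 1.46 for ILMN_2075643 and between -1.37 and -1.09 for ILMN_1745785, and leaving out a TOV112D array changes only the spread estimate and the p-values in ES2.

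**Figure D2:**
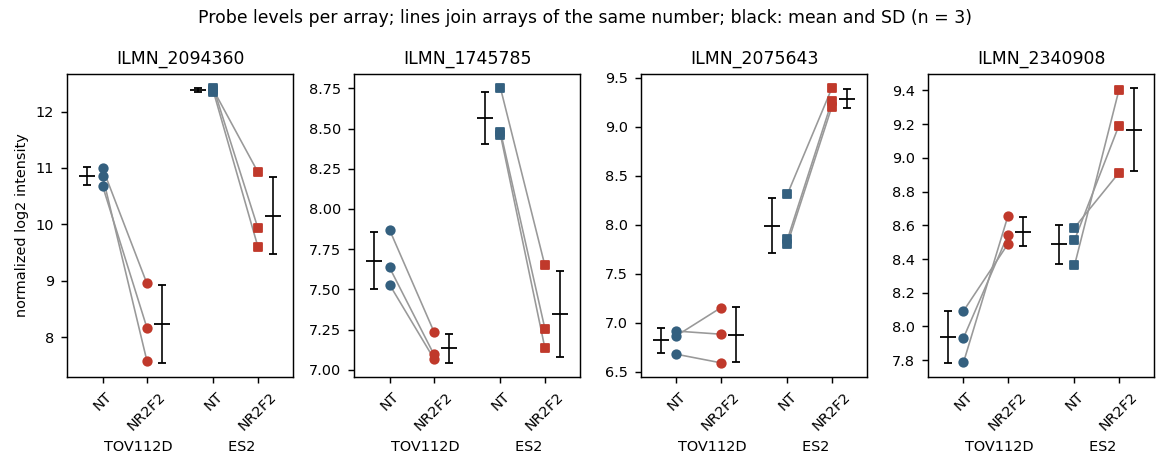
Normalized log2 intensity (vertical axis) of 4 probes on each array, by cell line and siRNA (NT, non-targeting; NR2F2, NR2F2 siRNA). Points are arrays, grey lines join arrays of the same number, and black bars show the group mean and SD (n = 3); ILMN_2094360 was lower with the NR2F2 siRNA in all 6 pairs, and ILMN_2075643 was higher in the 3 ES2 pairs.

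Whether the response differed between the lines was tested as the difference of both effects. An siRNA concentration is stated only for ES2, and the NR2F2 level was not read in either line. The line therefore cannot be told apart from dose or depth of knockdown. No probe passed in limma (0 of 28257, smallest adjusted p = 0.377), with 809 at an unadjusted p under 0.05 where 1413 are expected by chance. As in TOV112D, a count below chance from this model is not evidence that the lines responded alike. The replicate block also called 0 (smallest adjusted p = 0.0556), with 2052 at an unadjusted p under 0.05. For ILMN_2075643 the log2 difference was 1.30 in ES2 and 0.06 in TOV112D, where its mean level of 6.82 with the non-targeting siRNA lay below the filter value of 6.88. The difference of these effects, 1.24 (SE 0.22), did not pass (limma adjusted p = 0.912). ILMN_1745785 was lower in both lines, with -0.55 in TOV112D and -1.22 in ES2, and these effects did not differ past the threshold (limma adjusted p = 1.000). Of the 8 probes called in ES2, 5 had the same sign in TOV112D. For all 8 the effects differed between the lines at an unadjusted p under 0.05, and for 90 of the 104 called with the block. These probes were chosen for their ES2 effect, which raises such counts. Settings added after the data were seen called 23 probes for the difference (array weights with the block) and 22 (the block without the TOV112D number 2 pair). Under the settings fixed beforehand no call is shown to be specific to ES2.

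The transcripts changed alike in both lines were counted by direction. The lines share no control arrays. At the adjusted threshold the overlap was 0 probes without the block and 2 with it, both lower, where 0.0028 are expected from independent lists (one-sided Fisher exact p = 1.95e-06). With each line fitted alone with the block, a setting added after the data were seen, 0 were called in TOV112D and 0 in both, ILMN_2094360 having a limma adjusted p of 0.333 in TOV112D. At an unadjusted p under 0.01, 83 probes were lower in TOV112D and 132 in ES2, and 20 were lower in both, against 0.388 expected (one-sided Fisher exact p = 3.49e-29). For higher probes the lists held 92 and 218, with 2 in both against 0.710 expected (one-sided Fisher exact p = 0.159). All Fisher tests given here take probes as independent, which they are not, so their p-values are too small. Both lines also share 1 spread estimate per probe in these models, so a probe with a small estimate can enter both lists. The expected counts are therefore too low as well. Over 100 drawn splits of the arrays within lines, 4, the real one included, gave a shared count in 1 direction of at least 20. The shared lower count was 14 with values as deposited, 11 with array medians matched, and 13 without the ES2 non-targeting array 3 or the ES2 NR2F2 siRNA array 4. The 20 shared lower probes, chosen from these same arrays, were lower in all 6 pairs. Their median log2 differences were -0.59 in TOV112D and -0.61 in ES2, and 3 of them reached 2-fold in both lines. With the block the shared lower count was 46 against 3.77 expected, and the shared higher count was 26 against 7.57 (one-sided Fisher exact p = 5.12e-36 and 6.12e-08). Across all tested probes, which are not independent replicates, the fold changes of the lines correlated at r = 0.188, and 54.1% had the same sign.

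**Figure D3:**
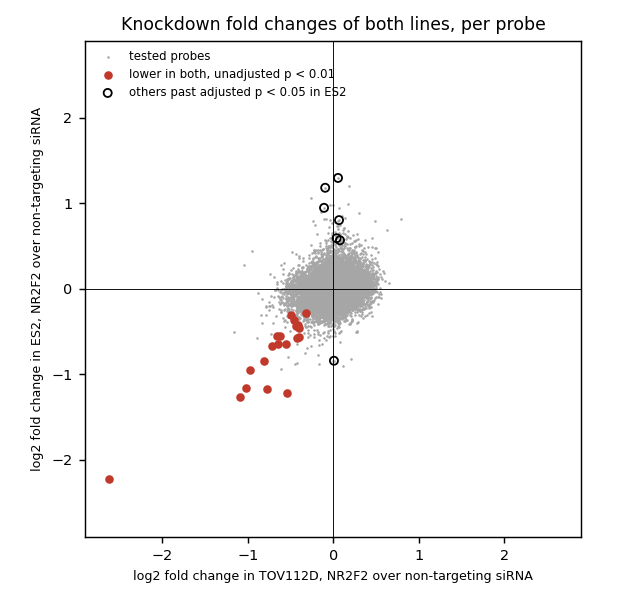
Log2 fold change of NR2F2 over non-targeting siRNA in TOV112D (horizontal axis) and ES2 (vertical axis) for the 28257 tested probes in grey. Red points are the 20 probes lower in both lines at an unadjusted p under 0.01, open circles the other 7 probes called in ES2; the probe at the lower left is ILMN_2094360, at -2.62 and -2.23.

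Averaged over both lines, 9 probes were called, 2 higher and 7 lower with the NR2F2 siRNA. All 9 had the same direction in all 6 pairs, whose arrays also gave the calls. ILMN_2094360 fell most, by 2.42 on the log2 scale (SE 0.24, 5.36-fold, limma adjusted p = 0.0096). ILMN_1745785, named from the ES2 contrast, fell by 0.88 (SE 0.10, limma adjusted p = 0.0134). It was not the next largest fall, as another called probe fell by 1.09. ILMN_2340908 rose by 0.65 (SE 0.09, 1.57-fold, limma adjusted p = 0.0395). The call of ILMN_2340908 held in 10 of the 24 other settings (adjusted p between 0.0024 and 0.1997), with log2 differences between 0.59 and 0.75. The smallest called fall was -0.43 and the smallest called rise 0.47. Of the 9 probes, 1 was also called in the ES2 contrast. With the replicate block 80 were called, 36 higher and 44 lower, including the 9, and 65 of the 80 had 1 direction in all 6 pairs.

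The split of the averaged calls moved with the scaling: 22.2% were higher as analysed, 12.5% of 8 calls with values as deposited and 0% of 3 calls with array medians matched. Their number was 0 without the TOV112D non-targeting array 1, the ES2 NR2F2 siRNA array 3 or the ES2 non-targeting arrays 3 or 4. It was 3 without the TOV112D non-targeting array 2 or the ES2 NR2F2 siRNA array 4, 5 without the TOV112D non-targeting array 4, and 16 without the ES2 NR2F2 siRNA array 5.

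The lines themselves were compared in the non-targeting arrays. Of the tested probes, 12446 (44.0%) differed, 6030 higher and 6416 lower in ES2 than in TOV112D. The median size of these differences was 0.77 on the log2 scale. At least 2-fold differences numbered 4430, of which 2135 were higher in ES2 and 2295 lower. Differences of 16-fold or more numbered 300, with 187 higher in ES2 and 113 lower. On all 3 control arrays of ES2 and on none of TOV112D, 984 probes exceeded the filter value, and 878 of these were called. The opposite held for 1165 probes, of which 1055 were called. Among the 18800 probes above that value on all 6 control arrays, 9035 were called, 4463 higher and 4572 lower in ES2. The share of higher calls was 48.4%, and 39.4% with values as deposited.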

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

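Combinations of settings named as added were chosen after seeing the data; the others were planned. The cause of a change was not tested unless stated. No direction of a named probe reversed under any setting. The TOV112D count stayed 0 under the other normalizations, filters, floor, separate fits, moderation and thresholds, was 2 with the replicate block, 1 with array weights, and 0 to 1 leaving out each array (1 without the NR2F2 siRNA array 4 of TOV112D or 5 of ES2). The ES2 count of 8 became 5 with values as deposited, 16 without a filter, 3 with the filter at the 75th percentile, 34 with each line fitted alone, 104 with the replicate block, 217 with array weights and 0 at an adjusted p under 0.01, and ranged from 0 to 31 leaving out each array. The averaged count of 9 became 3 with array medians matched, 80 with the replicate block, 65 with array weights and 2 at an adjusted p under 0.01, and ranged from 0 to 16. The count for the difference between lines stayed 0 in all planned settings in which it can be formed and leaving out each array (0 to 0). Probes called in both lines numbered 2 with the replicate block, 1 with array weights and 0 to 1 leaving out each array (1 without those same arrays). Of the 12446 differences between lines, 8161 were at least 1.5-fold, and the count ranged from 10723 to 13287 leaving out each array. The replicate block changed no other call of a comparison.

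Each line fitted alone with the replicate block called 450 probes in ES2, 0 in TOV112D and 0 in both, under added settings. Array weights with the replicate block called 10 in TOV112D, 604 in ES2, 9 in both lines, 261 on average and 23 for the difference. The replicate block without the TOV112D number 2 pair called 9, 635, 8, 269 and 22, so that a difference between the lines was called only in these last settings. Numbers 3 and 4 of ES2 alone called 416, and numbers 1 and 2 of TOV112D alone 0. Separate fits per line cannot give the difference or the average, and the block cannot give the contrast between lines. Testing all probes of a gene separately is identical here to the setting used, and the NR2F2 level and gene lists were not run. Dim probes limit what can be said: 20546 were not tested.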

Other observations

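The tests of the TOV112D count and of the difference between lines over other splits, of the averaged count and shared falls without the block over splits that part all pairs, of the shared falls without 1 array and of a brightness-dependent response were chosen after the result was seen.

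A hypothesis was that probes called in ES2 from numbers 3 and 4 alone would move alike in arrays that did not enter that call. Of these 416 probes, 93.3% had the same sign in the held-out number 5 pair, against 55.8% of the 27841 other probes. The median difference in the called direction was 0.27 on the log2 scale in that pair, and 0.53 and 0.56 in the pairs 3 and 4, which are raised by the selection. In TOV112D, 70.9% had the same sign, against 55.0% of the other probes, and the highest share under the other of the 20 labellings of its 6 arrays was 65.1%; the share was 78.8% for the 165 that fell in ES2 and 65.7% for the 251 that rose. The ES2 response may thus extend to the number 5 arrays, whereas the TOV112D share lies between the bounds set for a common response (over 75%) and for none (at most 60%) and leaves that open.

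Falls shared by both lines were a pattern to weigh: 20 probes were lower in both at an unadjusted p under 0.01. Among the 32 splits that part all pairs, with the replicate block, only the real split reached 46, and the highest other was 6. That share, 1 of 32, is the smallest these splits can give. It argues against chance for that model without excluding it. The choice of normalization and the TOV112D NR2F2 siRNA array 2 are argued against, as whole causes. The shared count fell to 14 and 11 under the other normalizations and to 16 without that array. Expected counts fell too, and the ratios were at least 99.0 and 67.3. These ratios are too high to an unknown degree, because both lines share 1 spread estimate per probe. Effects of the siRNA on other transcripts may account for these 20 falls as well as loss of NR2F2, and these cannot be told apart, because siRNA sequences, further siRNAs and probe annotation were not used here. Whether any of the 20, such as ILMN_2094360, is a probe of NR2F2 itself could not be read either.

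The TOV112D NR2F2 siRNA array 2 stood apart from its line. Admixed ES2 RNA is argued against: probes bright in ES2 and dim in TOV112D exceeded probes dim in both by 0.0201 on the log2 scale on this array, against a bound of 0.2 and a highest value of 0.0098 on the other TOV112D arrays. A monotone brightness-dependent response would be removed by quantile normalization, but its highest correlation with another TOV112D array was still 0.986 afterwards, below the 0.997 among the other arrays of numbers 1 and 2. A larger knockdown response could be the source, and its difference from the number 1 knockdown array correlated with the ES2 fold changes at r = 0.0589 across probes, between the bounds of 0.2 and 0, which leaves it open. RNA quality and hybridization were not tested. Array 2 was not alone in standing apart. The number 4 arrays correlated at most at 0.984 with the other TOV112D arrays, but at 0.996 with each other.

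Other splits of the arrays bear on the counts of calls. The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. In ES2 the real split gave 8 calls and the highest other 0 (1 of 10 splits as large), and with the replicate block 104 and 0 (1 of 4, again too few). In TOV112D the real split gave 0 calls, so all 10 had to be as large, which says nothing about chance. The highest, 1782, set the number 1 arrays and the non-targeting array 2 against the number 4 arrays and the NR2F2 siRNA array 2. That points to a structure of the arrays other than the siRNA. Between the control arrays of the lines the real split gave 12446 and the highest other 0 (1 of 10). For the averaged effect, 14 of 100 drawn splits within lines gave at least 9 calls, with a highest of 586, so chance is not excluded over such splits. All 13 others used that same TOV112D division, which leaves the TOV112D pairs 1 and 4 together and parts pair 2. Among the 32 splits that part all pairs, only the real one gave as many as 9, and the highest other gave 0. A share of 1 of 32 is the smallest reachable, so it argues against chance among these splits without excluding it. For the 20 shared falls, 4 of the 100, the real split among them, gave a shared count in 1 direction at least as large. The highest other was 30, and the other 3 again used that division. This share lies just under 0.05 and could change with another draw, so chance is not excluded over such splits. Among the 32 splits that part all pairs, 1 reached 20 and the highest other was 2. With the replicate block, 1 of those 32 splits, the real one, gave as many averaged calls as the real 80, the highest other being 1. This again is the smallest share reachable and does not exclude chance. For the difference between lines the real count was 0, so all 100 had to be as large, which says nothing about chance. The highest was 688.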
